A study of Arabidopsis thaliana with 9 samples.

How the data were processed

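RNA and accessible chromatin were measured in roots of Arabidopsis thaliana Col-0 seedlings. Per the labels' protocols, nuclei came from chopped and filtered whole roots of 7-day-old plants and were sorted by flow cytometry before single-nucleus library preparation, with 5 RNA and 2 ATAC libraries. The bulk RNA libraries came from 6-day-old plants, 1 from intact root tips and 1 from root tip protoplasts. The title and column name of the intact library read whole root, so a difference in tissue between the bulk libraries cannot be excluded. Plants of different ages were also grown under different light and temperature, per the labels.

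The bulk table holds FPKM values (fragments per unit of transcript length and of mapped library) that the authors deposited, for 33550 genes. Per the submitters' processing notes, bulk reads were checked with FastQC, aligned with TopHat2 2.0.11 and Bowtie2 2.1.0 and handled with SAMtools 0.1.19. The nucleus and whole-cell tables hold 1 average signal per gene and cluster, as deposited, and each of their columns sums to 10000, so they are averages of values scaled to 10000 per nucleus or cell. The accessibility table holds 1 average signal per region and cluster, as deposited, with column totals from 10532 to 14125. Per the submitters' processing notes, Cell Ranger 3.1.0, Cell Ranger ATAC 1.2, Seurat 3.1.5 and Signac 0.2.5 were used for the nuclei, on the TAIR10 build. The whole-cell table has no sample in the labels, so its plants, preparation and counting are unknown. The labels do not say how droplets with more than 1 nucleus or cell were treated in the cluster averages. Read counts could not be recovered from any table, so depth and the precision it gives are unknown. The 5 RNA and 2 ATAC libraries are pooled in the averages, which leaves no replicate value in any table, and therefore no p-value is given.

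Values were computed with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with Matplotlib 3.10.9. For the bulk libraries, log2(FPKM + 1) was compared among nuclear genes at 5 FPKM or more in either library. For the cluster tables and the accessibility table each column was scaled to 10000. Whole cells and nuclei were compared on the mean over clusters, each cluster weighted equally, as log2(mean + 0.1), among genes at 0.5 per 10000 or more in either mean. Genes listed at 0 in every cluster of a table had no ratio. Fold differences between bulk libraries and between whole cells and nuclei are on these scales, so they are smaller than the plain ratio of the values for low genes. Ratios of a cluster to the next cluster are plain ratios with nothing added. A gene counted as higher or lower at 2-fold and as strongly so at 4-fold. The median log2 ratio of each list was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. This percentile describes these libraries only, since genes are not independent replicates.

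A marker was read in the cluster with its highest value if that reached 0.5 per 10000, and a cluster was called like a cell type from 3 or more markers. Leading genes of a cluster were those at 1 per 10000 or more and at least 4-fold above every other cluster. Cluster correspondence was the Spearman correlation across genes of values centred per gene over clusters. Accessibility of a gene was the value of the regions that overlap it by 1 bp or more, and was compared with nucleus expression over the 21 clusters by Spearman correlation, with 1000 shuffles of the cluster names. Genes at 0.5 per 10000 or more in their highest nucleus cluster were used, which is the reading taken of a plan that did not say whether the floor applied to the mean or to the highest cluster. Gene names, lengths and positions for the region joins came from a RefSeq gene table of the TAIR10.1 assembly, in which all 23241 genes of the cluster tables were found. Accessible regions are given in the coordinates of the deposited file.

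The comparisons, the 13 marker lists (127 genes) and 7 other lists, and the rule for the genes named were chosen before the data were examined. Named were the 12 genes with the largest increase and the 12 with the largest decrease among nuclear genes past the floor that have a symbol, in the bulk and in the whole-cell comparison. Also named were the markers read in a cluster, the 3 genes of each cluster with the largest ratio to the next cluster, the 6 markers with the highest and the 6 with the lowest accessibility correlation, and members of each list with the largest change. JAZ6, PROPEP1, MT1A and the gene AT1G07590 were named after their values were seen. Of the bulk genes past the floor, 320 had exactly the same pair of values as another gene, so these values are uncertain.

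The calculations were tested on simulated data. With 200 of 15110 bulk genes changed, 90% were called at a 2.5-fold change and 100% at 4-fold and at 8-fold, and 0% of the unchanged genes. The simulated noise was chosen well under 2-fold, and every simulated intact level was set to 5 FPKM or more. The real error between the bulk libraries is unknown, so these shares are not error rates of the 2-fold calls. Of 200 lists with no effect, 5% fell outside the middle 95% of random lists. All 21 simulated clusters were matched to their source, and 0 of 200 region joins differed from a direct search. Alternatives covered the pseudocounts, the floors, the fold thresholds, the centring of ratios, the way clusters were averaged, the list sizes and the correlation used. A value counted as the same under an alternative when it stayed within 1.5-fold, or within 0.1 for correlations.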

Results

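The series measured RNA and chromatin accessibility in roots of Arabidopsis thaliana seedlings. It held 9 samples: 5 single-nucleus RNA libraries and 2 single-nucleus accessibility libraries from whole roots of 7-day-old plants, and 2 bulk RNA libraries from root tips of 6-day-old plants. Of the bulk libraries, 1 came from intact tips, although its title reads whole root, and 1 from protoplasts. Protoplasts are cells whose walls were removed with enzymes. Accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin. The nucleus libraries were available as 1 average per gene and cluster over pooled nuclei, for 23241 genes and 21 numbered clusters. A second table of the same genes held averages over whole cells in 20 clusters, with no cluster 14. Its plants and its preparation are not described in the labels. No value therefore has a replicate error, and every difference below describes these libraries and tables. The sequencing depth of the libraries and the number of nuclei or cells per cluster could not be read from the values.

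The first comparison asked which transcripts differed after the walls were digested. Most of the listed jasmonate, heat shock and oxidative stress genes at 5 FPKM or more were higher in the protoplast library, and all listed ribosomal protein genes were lower. The ethylene response factor ABR1 (AT5G64750) was at 0.499 FPKM in intact tips and 238 in protoplasts, and the drought and heat regulator DREB2A (AT5G05410) was at 19.5 and 1979.6, a 96.5-fold difference after 1 FPKM was added to each. The auxin response repressor IAA5 (AT1G15580) was 59.5-fold higher, SRO5 (AT5G62520) 45.2-fold, the galactinol synthase GolS2 (AT1G56600) 39.6-fold and the glutathione transferase GSTU11 (AT1G69930) 38.0-fold. The peptide precursor gene PSK6 (AT4G37720) was 37.3-fold higher, EDL3 (AT3G63060) 36.2-fold, PMAT2 (AT3G29670) 34.4-fold and the copper-binding protein gene BCB (AT5G20230) 34.2-fold. The small RNA genes U49.1 (AT4G05048) and MIR418 (AT3G18895) were listed at 0 in intact tips and at 61.5 and 46.7 FPKM in protoplasts, but MIR418 shared its pair of values exactly with other genes, so its value is uncertain. Among the lowest, the neighbouring and similar genes MLP328 (AT2G01520) and MLP329 (AT2G01530) were at 266 and 761 FPKM in intact tips and at 0.112 and 2.77 in protoplasts, so their reads could be shared. The protease inhibitor-like gene DR4 (AT1G73330) was at 2156 FPKM in intact tips and 19.2 in protoplasts. The glycine-rich protein gene GRP9 (AT2G05440) was 113.0-fold lower, the cell wall enzyme gene XTH31 (AT3G44990) 101-fold, the lipid transfer protein gene EARLI1 (AT4G12480) 97.2-fold, the laccase gene LAC7 (AT3G09220) 70.6-fold, the oxylipin-forming dioxygenase gene DOX1 (AT3G01420) 61.5-fold and MLP43 (AT1G70890) 55.2-fold. AZI1 (AT4G12470), U60.1F (AT5G52471) and U60.2F (AT4G25631) were listed at 0 in protoplasts and at 77.6, 142 and 74.9 FPKM in intact tips, and the values of U60.1F and U60.2F are uncertain for the same reason.

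Of 15110 nuclear genes at 5 FPKM or more in either library, 1718 were at least 2-fold higher in protoplasts and 4582 were at least 2-fold lower. The 4-fold counts were 727 and 1465. The median gene had a log2 ratio of -0.46, and with ratios centred on it 2632 genes were higher and 2845 lower. The share of changed genes that were higher was then 48.1% in place of 27.3%. Bulk medians of lists with 3 or more genes are therefore also given relative to that median, and each such list is placed by its percentile among 10000 random lists of the same size and mean expression. The 2 libraries had a Spearman correlation of 0.716 across these genes, which are not independent replicates.

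Of the 17 jasmonate genes past the floor, 15 were 2-fold higher and 1, JAZ6 (AT1G72450), was lower. Their median log2 ratio was 2.25, or 2.70 above the median gene, at percentile 100. The biosynthesis enzyme gene AOC1 (AT3G25760) was 28.6-fold higher, at 58.9 FPKM in protoplasts, and the repressor genes JAZ8 (AT1G30135) and JAZ2 (AT1G74950) were at 3.44 and 68.0 and at 109.8 and 961. Of 13 heat shock genes, 11 were higher and none lower, with a median of 2.30, or 2.76 above the median gene, at percentile 100. The chaperone gene BIP3 (AT1G09080) was at 0.112 and 18.6 FPKM and the heat shock factor gene HSFA2 (AT2G26150) at 0.801 and 17.9. Of 11 oxidative stress and detoxification genes, 7 were higher and 1 lower, with a median of 1.94, or 2.39 above the median gene, at percentile 100. CYP81D8 (AT4G37370) was 24.8-fold higher and GSTU25 (AT1G17180) 12.5-fold, while GSTF7 (AT1G02920) was 6.27-fold lower. The 23 wound, touch and immune response genes split, with 9 higher, 6 lower and a median of 0.17, or 0.62 above the median gene, at percentile 93.6. The transcription factor gene ERF115 (AT5G07310) and the touch gene TCH4 (AT5G57560) were 20.6-fold and 7.83-fold higher, and CAF1A (AT3G44260) and ERF105 (AT5G51190) were 14.2-fold and 8.82-fold lower.

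All 17 cytosolic ribosomal protein genes were 2-fold lower in protoplasts, and all 17 stayed so after centring. Their median was -1.83, or -1.37 relative to the median gene, at percentile 0. RPL5B (AT5G39740) was at 452 FPKM in intact tips and 68.8 in protoplasts and RPS18A (AT1G22780) at 247 and 47.7. Of the 12 plastid-encoded genes past the floor, 11 were lower and 1 higher, with a median of -3.52, and of 4 mitochondrial ones 3 were lower. The 4 photosynthesis genes of the nucleus past the floor were all lower, with a median of -3.59, or -3.14 relative to the median gene, at percentile 0, but 33.1 with no floor and 7.74 with a floor of 20 FPKM. The light-harvesting gene LHCB1.3 (AT1G29930) was at 25.8 and 0.705 FPKM and the Rubisco activase gene RCA (AT2G39730) at 28.3 and 1.41. MT1A (AT1G07600), a metallothionein gene that shared its pair of values exactly with the overlapping entry AT1G07590, made up 3.85% of the summed FPKM in intact tips and 0.674% in protoplasts. Among the 6 common reference genes, the polyubiquitin gene UBQ10 (AT4G05320) was 2.34-fold higher and the other 5 differed by less than 2-fold. They included ACT2 (AT3G18780), at 917 and 1058 FPKM, and their median of 0.07, or 0.53 above the median gene, was at percentile 68.1.

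Markers of cell types did not move together. Of 15 endodermis markers, 9 were 2-fold lower and none higher, with a median of -1.19, or -0.73 relative to the median gene, at percentile 1.53. ASFT (AT5G41040), of suberin synthesis, was 13.8-fold lower, and CYP86A1 (AT5G58860) was at 5.10 FPKM in intact tips and listed at 0 in protoplasts. The regulator gene SCR (AT3G54220) was 6.08-fold lower. Of 4 pericycle markers, 3 were lower: the nitrate transporter gene NPF7.3 (AT1G32450) by 29.2-fold, the phosphate exporter gene PHO1 (AT3G23430) by 9.66-fold and the boron transporter gene BOR1 (AT2G47160) by 8.86-fold. Their median was -3.21, or -2.75 relative to the median gene, at percentile 0.04. With a floor of 20 FPKM the endodermis and pericycle percentiles were 2.79 and 10.8, and with no floor that of pericycle was 13.96. Of 11 xylem markers, 2 were higher and 1 was lower, with a median of 0.66, or 1.11 above the median gene, at percentile 99.9, but 93.9 with a floor of 20 FPKM. After centring 7 were higher and 1 was lower. MC9 (AT5G04200) was 4.97-fold higher and TED6 (AT1G43790) 8.33-fold lower, and MC9 was highest in nucleus cluster 4 (3.65), with 0.884 in the xylem-like cluster 21. Of 5 root cap markers, 3 were higher and 1 was lower, with a median of 1.37, or 1.82 above the median gene, at percentile 99.7, and at 86.4 with no floor. Among them BRN1 (AT1G33280) was at 14.7 and 67.6 FPKM and BRN2 (AT4G10350) at 7.36 and 32.0. All 8 mitosis markers and 6 of 8 DNA replication markers were 2-fold lower, with medians of -1.19 and -0.79 relative to the median gene, at percentiles of 5.96 and 4.85, and after centring 4 and 2 were. The cyclin gene CYCB1;3 (AT3G11520) was 5.55-fold lower and CDC20.1 (AT4G33270) 4.38-fold, and the replication genes PCNA1 (AT1G07370) and HIS4 (AT2G28740) were 3.75-fold and 3.36-fold lower. The 15 root hair markers had a median of -0.56, or -0.10 relative to the median gene, at percentile 4.70, with 2 higher and 3 lower. RHD6 (AT1G66470) was 6.87-fold higher and XTH26 (AT4G28850) 4.89-fold lower. Of the 6 non-hair markers, 2 were higher, MYB23 (AT5G40330) by 4.53-fold and CPC (AT2G46410) by 2.65-fold, and their median was 0.92 above the median gene, at percentile 93.9. None of 4 cortex genes and 2 of 6 stele genes (SHR (AT4G37650) and LHW (AT2G27230), both lower) changed 2-fold, with medians 0.26 and 0.07 above the median gene, at percentiles of 71.8 and 67.8. Of 5 mineral uptake genes 2 were higher and 1 was lower, with a median 0.62 above the median gene at percentile 86.4, the iron reductase gene FRO2 (AT1G01580) being 3.22-fold higher and the iron transporter gene IRT1 (AT4G19690) 8.00-fold lower. Only 2 phloem genes passed the floor, of which SUC2 (AT1G22710), a sucrose transporter gene, was 6.93-fold higher and PP2-A1 (AT4G19840) 5.88-fold lower. The stem cell niche gene AGL42 (AT5G62165) was 2.95-fold lower and was the 1 member past the floor.

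**Figure D1:**
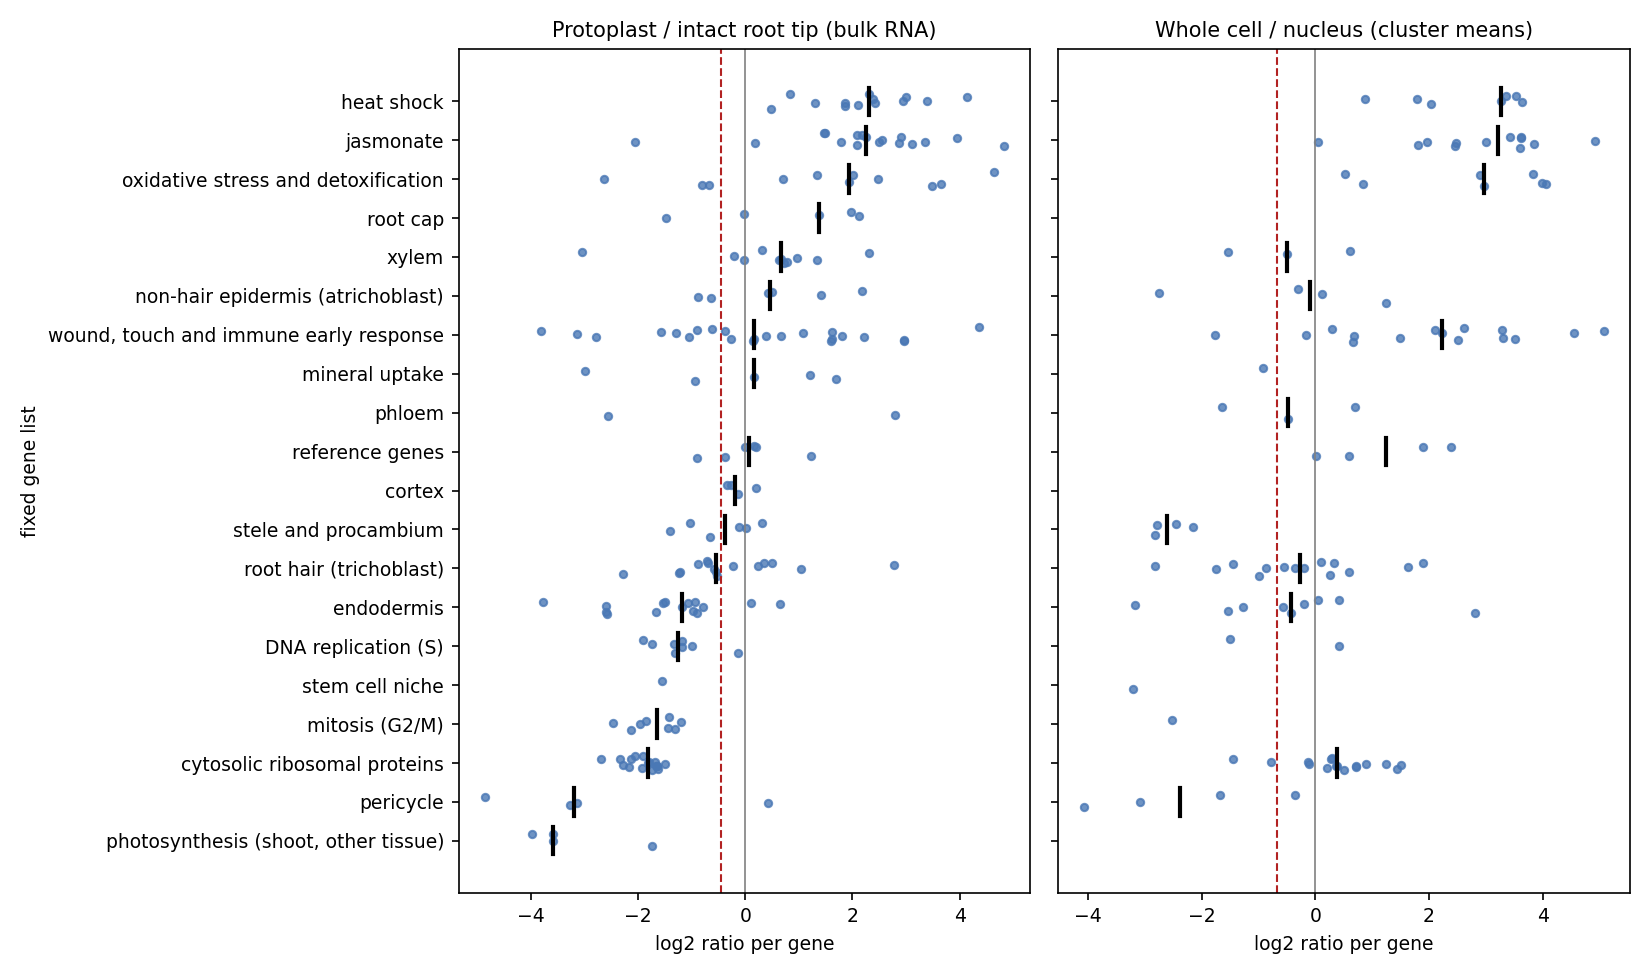
Log2 ratio of each listed gene past the floor, protoplast to intact root tip FPKM on the left and whole-cell to nucleus cluster means on the right, by fixed gene list. Each point is a gene, the black bar is the median of a list with 3 or more genes, the dashed line is the median of all genes, and jasmonate, heat shock and oxidative stress lists lie to the right in both panels.

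The second comparison asked which cell types the 21 clusters of root nuclei held. Markers for 13 cell types or states had been fixed in advance, and 99 of 127 markers reached 0.5 per 10000 in their highest cluster. Root hair genes were highest in cluster 1 (10 of 15) and cluster 2 (4 of 15). The proline-rich wall protein gene PRP3 (AT3G62680) was at 164 per 10000 in cluster 1 and 29.3 in cluster 2, XTH14 (AT4G25820) was at 74.4 and 30.1, and the expansin gene EXPA7 (AT1G12560) was at 30.7 in cluster 2 and 14.5 in cluster 1. RHD6, an early regulator of hair growth, was highest in cluster 3 at 1.43. Non-hair genes led cluster 6 (3 of 5), with the homeodomain gene GL2 (AT1G79840) at 1.51 and XTH17 (AT1G65310) at 18.1. The others, ABCB4 (AT2G47000) and WER (AT5G14750), were highest in clusters 4 and 7, at 9.29 and 2.66. The stele gene WOL (AT2G01830) was also highest in cluster 6, at 6.91. Casparian strip genes marked cluster 16, which held the highest value of 10 of 16 endodermis genes. CASP1 (AT2G36100) reached 93.3 there against 2.69 in the next cluster, ESB1 (AT2G28670) 69.2 against 2.60 and the peroxidase gene PER64 (AT5G42180) 57.0 against 1.99. The suberin genes FAR4 (AT3G44540), CYP86A1 and GPAT5 (AT3G11430) were instead highest in cluster 14, at 31.1, 22.4 and 6.32.

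In the inner tissues, 3 of 6 pericycle genes were highest in cluster 18, with NPF7.3 at 22.7, PHO1 at 11.4 and the sodium transporter gene HKT1 (AT4G10310) at 1.55. Cluster 19 held 5 of 9 phloem genes, among them the companion cell genes PP2-A1 at 11.4 and SUC2 at 8.93 and the phloem regulator gene APL (AT1G79430) at 7.99. Another 3 phloem genes, CVP2 (AT1G05470), PEAR1 (AT2G37590) and CALS7 (AT1G06490), were highest in cluster 17 at 2.14, 0.740 and 0.655. Cluster 21 held 11 of 12 xylem genes, with the proteases XCP2 (AT1G20850) and XCP1 (AT4G35350) at 27.8 and 21.2 and the secondary wall cellulose synthase gene CESA4 (AT5G44030) at 13.5. It also held 5 of 8 stele genes, with ATHB8 (AT4G32880) at 10.8 there and 6.01 in cluster 20, and PXY (AT5G61480) at 4.37. All 11 mitosis genes were highest in cluster 10, where CDC20.1 was at 24.7 against 0.886 in the next cluster and KNOLLE (AT1G08560) at 7.04 against 0.222. Of 8 DNA replication genes, 6 were highest in cluster 9, with TSO2 (AT3G27060) at 4.73 and the histone gene HIS4 at 3.42. By the rule of 3 or more markers, clusters 1 and 2 were root hair-like, 6 non-hair-like, 14 and 16 endodermis-like, 17 and 19 phloem-like, 18 pericycle-like and 21 both xylem-like and stele-like, with 9 and 10 marked by cell cycle genes. The other 10 clusters had no name. Cluster 7 held 2 root cap genes, SMB (AT1G79580) at 0.885 and BRN1 at 0.602, and cluster 12 held the 1 cortex gene past the floor, AT1G62510 at 0.675. The stem cell niche genes AGL42 and PLT1 (AT3G20840) were highest in clusters 15 and 7. Of 10 photosynthesis genes, 3 reached the floor, and none exceeded 1.14 per 10000.

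The 3 genes of each cluster that stood out most against the next cluster were mostly unlisted ones, and are given with their value there as a plain multiple of the next highest, which is large where the next value is near 0. In the root hair-like clusters they were the arabinogalactan protein gene FLA13 (AT5G44130, 8.68-fold), AT5G06630 (8.25-fold) and AT5G42510 (8.08-fold) in cluster 1, and AT1G70450 (10.0-fold), AT1G50930 (8.05-fold) and AT3G43930 (7.95-fold) in cluster 2. Cluster 6, non-hair-like, was led by the fatty acyl reductase gene CER4 (AT4G33790, 61.9-fold), AT1G06120 (48.6-fold) and AT4G01890 (29.7-fold). Cluster 14, with the suberin genes, was led by the transcription factor gene NAC038 (AT2G24430), at 7.72 against 0.0424, AT5G37690 (95.4-fold) and the pectin methylesterase gene QRT1 (AT5G55590, 88.9-fold). Cluster 16, with the Casparian strip genes, was led by AT5G51680 (287-fold), B70 (AT4G21340), at 13.9 against 0.143, and AT3G24020, at 34.0 against 0.378. The pericycle-like cluster 18 was led by NPF7.3 (19.2-fold) and the glucosinolate chain elongation genes MAM1 (AT5G23010), at 5.47 against 0.301, and IMS2 (AT5G23020, 16.2-fold). The phloem-like clusters were led by AT1G05813 (263-fold), AT2G26695 (218-fold) and AT2G40390 (151-fold) in cluster 19 and by AT3G57780 (7.52-fold), AT2G36570 (5.56-fold) and XTH20 (AT5G48070, 5.43-fold) in cluster 17. The xylem-like cluster 21 was led by the secondary wall regulator gene MYB46 (AT5G12870, 113-fold), the laccase gene LAC11 (AT5G03260, 98.2-fold) and the xylan synthesis gene GAUT12 (AT5G54690, 93.0-fold). Cluster 10 was led by AT5G37247 (77.5-fold), AT1G78865 (55.1-fold) and the spindle protein gene TPX2 (AT1G03780, 54.5-fold), and cluster 9 by ATGSTF13 (AT3G62760, 22.9-fold), AT5G10390 (6.64-fold) and AT4G01533 (4.92-fold).

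Among the unnamed clusters, cluster 11 was led by EARLI1 (16.0-fold), AZI1, at 6.48 against 0.443, and AT1G33100 (8.07-fold). Cluster 5 was led by IRT1, at 2.88 against 0.552, DXPS1 (AT3G21500, 4.80-fold) and AT1G29600 (4.07-fold). Cluster 7 was led by the myrosinase gene TGG1 (AT5G26000), at 1.25 against 0.00672, AT5G60530 (15.8-fold) and AT1G52060 (10.9-fold). Cluster 8 was led by GATA23 (AT5G26930, 25.4-fold), a regulator of lateral root founder cells, XTH21 (AT2G18800, 19.7-fold) and AT4G20210 (3.99-fold), and cluster 4 by AT3G54520 (22.0-fold), AT3G48346, at 1.26 against 0.0626, and the protease gene CEP1 (AT5G50260, 18.1-fold). The leading genes of cluster 3 were AT4G22217 (28.8-fold), CID5 (AT5G11440, 19.5-fold) and AT4G27480 (11.4-fold), and those of cluster 12 IAMT1 (AT5G55250, 6.48-fold), AT2G45180 (5.82-fold) and ELP (AT1G12090, 5.32-fold). Those of cluster 13 were the transporter gene OCT3 (AT1G16390, 44.8-fold), ALMT12 (AT4G17970, 17.5-fold) and AT5G45200 (15.9-fold). Those of cluster 15 were the tropinone reductase-like gene TRI (AT2G29330, 12.2-fold), AT5G19890 (8.16-fold) and GLIP2 (AT1G53940, 7.93-fold), and those of cluster 20 IQD12 (AT5G03960, 21.3-fold), AT2G26390 (18.8-fold) and the cytokinin oxidase gene CKX3 (AT5G56970, 18.6-fold). The number of genes at least 4-fold above every other cluster ranged from 2 in cluster 8 to 186 in cluster 10.

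**Figure D2:**
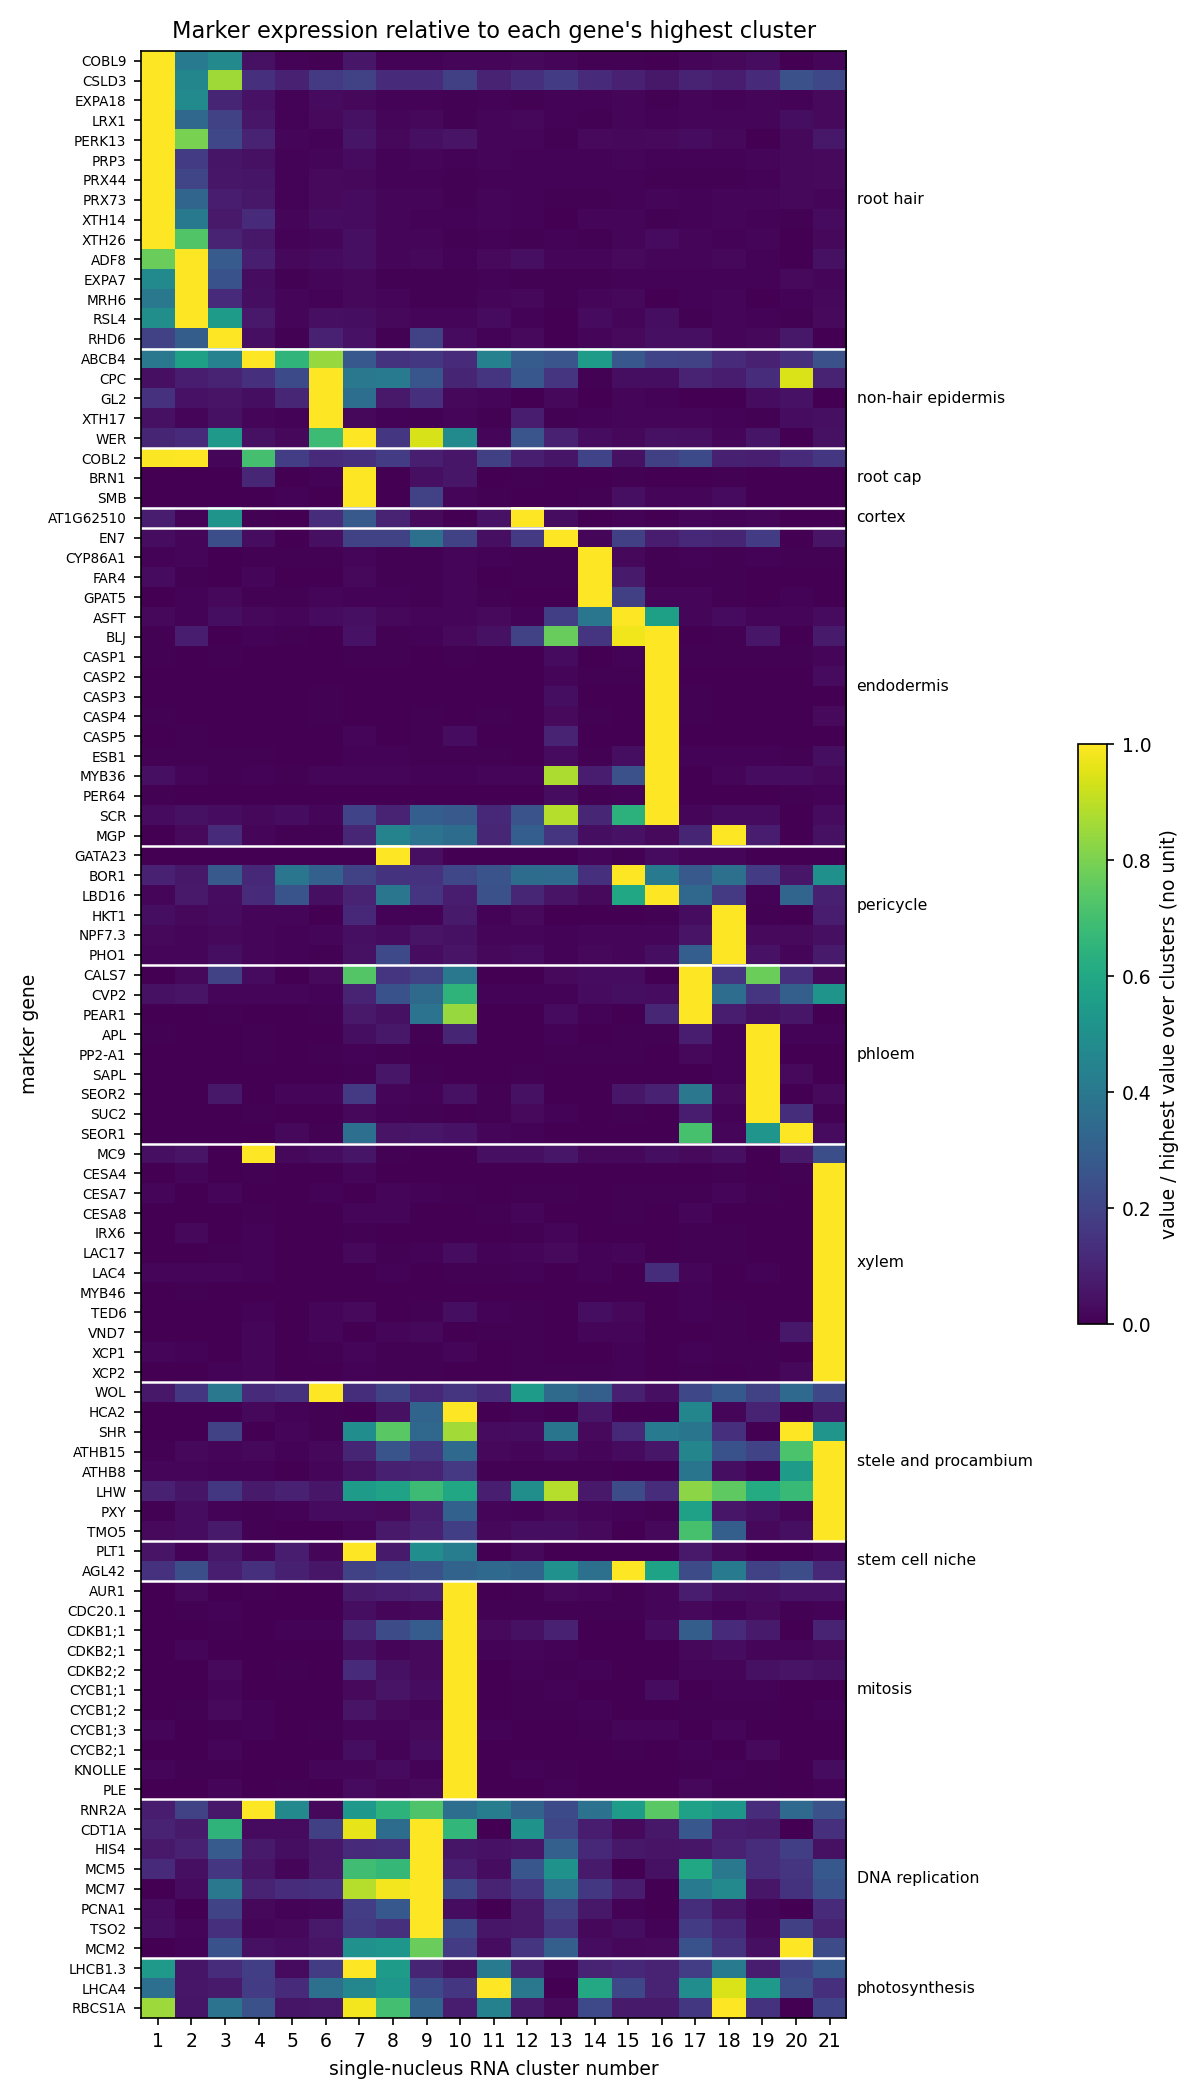
Value of each of the 99 markers that reached 0.5 per 10000, divided by its own highest value, in the 21 single-nucleus RNA clusters (columns), grouped by marker list (rows between white lines). Yellow marks a gene's highest cluster, which was cluster 10 for all 11 mitosis genes and cluster 21 for 11 of 12 xylem genes.

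The third comparison set whole cells against nuclei. BCB, SRO5 and ABR1, which were among the genes highest in the protoplast library, were also among the 12 named genes highest in whole cells. The desiccation protein gene LEA7 (AT1G52690) averaged 0.0273 per 10000 over nucleus clusters and 10.7 over whole-cell clusters. After 0.1 was added to each, BCB was 61.0-fold higher in whole cells, bZIP1 (AT5G49450) 57.0-fold, the calmodulin-like gene CML38 (AT1G76650) 49.6-fold, SRO5 48.5-fold, ASL5 (AT2G30130) 47.4-fold and DIP2 (AT5G03210) 44.3-fold. The salicylic acid glucosyltransferase gene UGT74F2 (AT2G43820), the dehydrin gene LTI30 (AT3G50970), LEA4-5 (AT5G06760), the zinc finger gene ZAT12 (AT5G59820) and ABR1 were 35.9-fold, 35.7-fold, 35.4-fold, 33.6-fold and 32.5-fold higher. Higher in nuclei were MLP328, at 18.1 against 0.000173, DR4, at 44.5 against 0.169, and MLP329, at 13.4 against 0.0472. DOX1 was 50.1-fold higher in nuclei, JAL22 (AT2G39310) 45.8-fold, GRP9 42.7-fold, the nuclear poly(A) polymerase gene nPAP (AT4G32850) 41.8-fold, TLL1 (AT1G45201) 40.1-fold, the amino acid permease gene AAP2 (AT5G09220) 36.6-fold, the linker histone gene HIS1-3 (AT2G18050) 32.0-fold, KCS2 (AT1G04220) 30.0-fold, and MYB59 (AT5G59780) was at 3.49 against 0.0497. Some of these differences were smaller within clusters. The median log2 ratio within clusters was -2.44 for TLL1, -2.63 for AAP2, -2.97 for HIS1-3, -2.70 for KCS2 and 4.65 for LEA7, against -5.33, -5.19, -5.00, -4.90 and 6.41 between the means. TLL1 reached 76.8 in nucleus cluster 14, which has no whole-cell column, and its log2 ratio was -2.61 without that cluster, and that of KCS2 -3.92. Each of these 24 genes had the same direction in all 20 clusters of the same number.

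Of 6513 genes with 0.5 per 10000 or more in either mean and values above 0 in both tables, 1309 were 2-fold higher in whole cells and 2831 in nuclei, with a median log2 ratio of -0.67. With ratios centred on it, 2097 genes were higher in whole cells and the share of changed genes that were so was 52.2% in place of 31.6%. With a floor of 2 per 10000 the counts were 663 and 352, so that the direction of the split depended on low genes. The Spearman correlation of the means across these genes was 0.105. Genes low in both means were left out of it, so it does not describe the likeness of the full profiles. Across 14697 genes, the nucleus mean had a correlation of 0.675 with the intact bulk library and the whole-cell mean 0.688. The ratio was lower for longer genes, with a Spearman correlation of -0.56 across genes. A further 12 genes past the floor were listed at 0 in every nucleus cluster and 21 in every whole-cell cluster.

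Of 12 jasmonate genes, 11 were 2-fold higher in whole cells and none lower, with a median of 3.21, or 3.88 above the median gene, at percentile 100. JAZ8 averaged 0.0158 in nuclei and 3.40 in whole cells, JAZ7 (AT2G34600) 0.0983 and 2.75, and JAZ10 (AT5G13220) 0.426 and 6.33. Of 7 heat shock genes 6 were higher (median 3.26, percentile 100), with HSP17.6II (AT5G12020) at 0.0224 and 1.42. Of 7 oxidative stress genes 5 were higher (median 2.97, percentile 100), with GSTF8 (AT2G47730) at 3.82 and 55.9 and GSTU25 at 0.585 and 11.3. Of 15 wound, touch and immune genes 10 were higher and 1, PROPEP1 (AT5G64900), was lower (median 2.23, percentile 100), with ZAT12 as above and ERF109 (AT4G34410) at 0.0151 and 2.60. Of 16 ribosomal protein genes 3 were higher and 1 was lower (median 0.37, percentile 21.8), with RPS5A (AT3G11940) 2.84-fold higher in whole cells and RPL4A (AT3G09630) 2.73-fold lower. With ratios centred on the median gene, 9 were higher and 0 lower. All 4 stele genes were higher in nuclei (median -2.61, percentile 1.54), with ATHB8 at 1.28 in nuclei and 0.0957 in whole cells and the cytokinin receptor gene WOL (AT2G01830) at 1.71 and 0.163, although the percentile was 15.4 when ratios were taken within clusters. Of 4 pericycle genes 3 were higher in nuclei, with NPF7.3 at 1.62 against 0.00246 and a percentile of 5.44. Of 14 root hair genes 2 were higher in whole cells and 3 in nuclei, with the peroxidase gene PRX44 (AT4G26010) at 4.32 in nuclei and 16.3 in whole cells and LRX1 (AT1G12040) at 2.05 and 0.206. That split turned to 4 in whole cells and 2 in nuclei after centring. Of 9 endodermis genes 1 was higher in whole cells, CASP5 (AT5G15290), and 3 in nuclei, the largest difference being that of ASFT, at 1.49 against 0.0758. Of 4 non-hair genes CPC was higher in whole cells and ABCB4 (AT2G47000) in nuclei. Of 3 phloem genes and 3 xylem genes, 1 each was higher in nuclei, PP2-A1 by 3.13-fold and CESA4 by 2.89-fold, and of the 2 DNA replication genes TSO2 was, by 2.81-fold. The only mitosis gene past the floor, CDC20.1, and the only stem cell niche gene, AGL42, were 5.75-fold and 9.18-fold higher in nuclei, the phosphate transporter gene PHT1;1 (AT5G43350) differed by 1.88-fold, and no cortex, root cap or photosynthesis gene passed the floor. Relative to the median gene, the list medians were 3.93 for heat shock, 3.64 for oxidative stress, 2.90 for wound, touch and immune, 1.04 for ribosomal protein, -1.94 for stele and -1.70 for pericycle genes. They were 1.92 for reference, 0.58 for non-hair, 0.40 for root hair, 0.24 for endodermis, 0.19 for phloem and 0.17 for xylem genes, at percentiles of 70.4, 49.2, 15.4, 24.2, 77.0 and 38.2. The suberin gene FAR4 averaged 1.80 in nuclei and CYP86A1 1.24, and each was listed at 0 in every whole-cell cluster. The reference genes ACT2 and GAPC1 (AT3G04120) were 5.21-fold and 3.74-fold higher in whole cells and the other 2 past the floor differed by less than 2-fold.

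The genes that differed between the bulk libraries were then followed into the whole-cell and nucleus tables. Of the 727 genes 4-fold higher in protoplasts, 340 had a whole-cell to nucleus ratio. Of these, 292 (85.9%) were 2-fold higher in whole cells and 4 in nuclei, with a median log2 ratio of 2.66 at percentile 100, compared with 1309 of all 6513 genes. Of the 1465 genes 4-fold lower in protoplasts, 503 had a ratio, 341 (67.8%) were higher in nuclei and 14 in whole cells, with a median of -1.96 at percentile 0. Of all genes 43.5% were higher in nuclei. The bulk and whole-cell ratios had a Spearman correlation of 0.443 across 6394 genes. Ribosomal protein genes did not follow this relation, with all 17 lower in protoplasts and 1 of 16 lower in whole cells, or 0 after centring. Across 14697 genes, the whole-cell mean had a correlation of 0.817 with the protoplast library and 0.688 with the intact library, and the nucleus mean had 0.525 and 0.675. The bulk libraries came from root tips of younger plants than the nuclei, so age, tissue and preparation differ together between them.

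**Figure D3:**
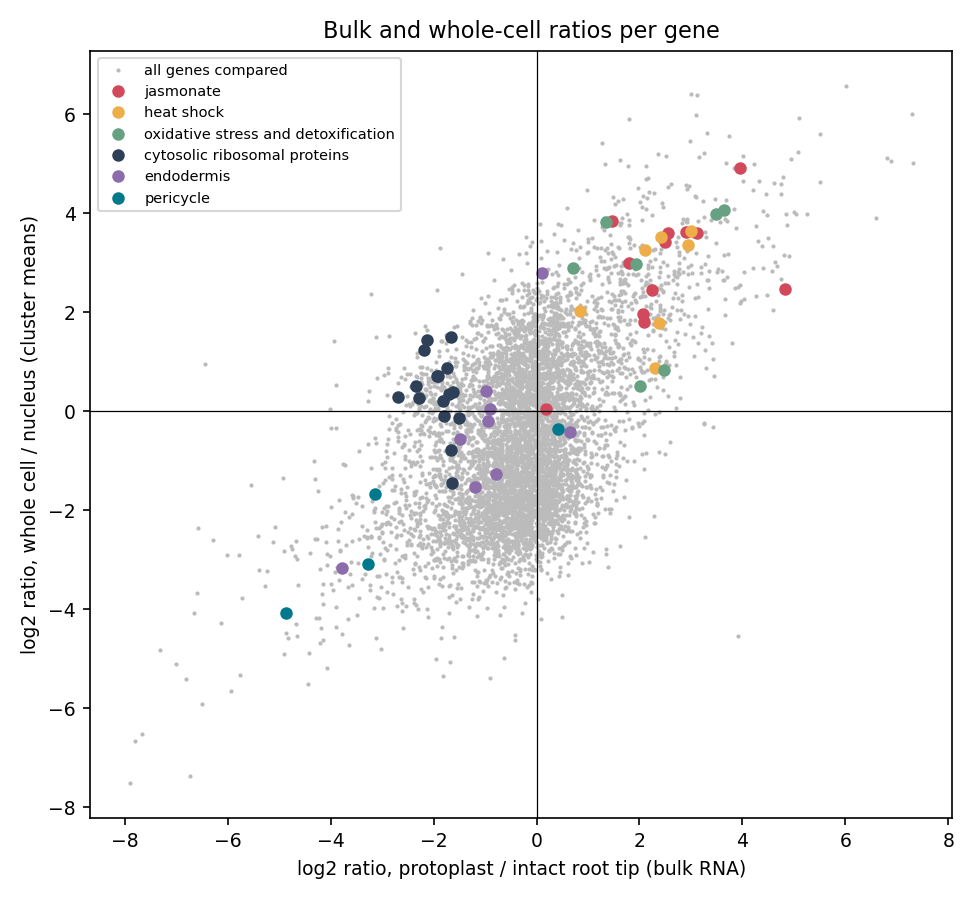
Each point is a gene, placed by its log2 ratio of protoplast to intact FPKM (horizontal axis) and of whole-cell to nucleus cluster means (vertical axis), with 6 fixed lists in colour. The 6394 genes had a Spearman correlation of 0.443, and ribosomal protein genes lie to the left of 0 with a median of 0.37 on the vertical axis.

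Whether cluster numbers meant the same population in each table was checked across genes, on values centred per gene. In whole cells, as in nuclei, cluster 1 held most root hair genes (12 of 15), cluster 16 most endodermis genes (7 of 10), cluster 21 most xylem genes (11 of 12) and cluster 10 most mitosis genes (10 of 10). Nucleus cluster 14, with the suberin genes, had no whole-cell cluster of its number, and its best partner was whole-cell cluster 16, at 0.399. Of 68 markers past the floor in both tables, 54 had the same highest cluster. Whole-cell cluster 12 held 3 cortex genes, and whole-cell cluster 10 also held 3 root cap genes. Over 3521 genes, same-numbered clusters had a median Spearman correlation of 0.642, from 0.381 in cluster 4 to 0.799 in cluster 2, against -0.039 between clusters of other numbers. For 16 of 20 whole-cell clusters the best nucleus cluster had the same number. The exceptions were cluster 10, which holds the mitosis genes and was closer to nucleus cluster 9 (0.583 against 0.499), cluster 19, with the phloem genes, closer to nucleus cluster 8 (0.604 against 0.521), cluster 11, closer to nucleus cluster 5 (0.605 against 0.552), and cluster 15, closer to nucleus cluster 16 (0.581 against 0.538). In the other direction 15 of 20 nucleus clusters were closest to their own number. Clusters 7, 10, 15 and 17 were not, nor was cluster 4, at 0.629 with whole-cell cluster 5 against 0.381 with its own number. How the authors numbered the clusters is not given in the sources used here, so matching numbers may not be independent of the values.

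The last comparison set chromatin accessibility against nucleus expression. The phosphate exporter gene PHO1 and the non-hair gene ABCB4 were most accessible in the cluster where they were most expressed, while the root hair gene PRP3 and the Casparian strip gene CASP1 were not. The file listed 20803 accessible regions (TAIR10 build) with a median length of 1715 bp, and 22573 genes (97.1%) overlapped at least 1. PHO1 overlapped regions on chromosome 3 at 8385337 to 8391306 and 8392804 to 8393867, and its accessibility in cluster 18 was 4.70 times its median over clusters. Its correlation with expression over the 21 clusters was 0.774. ABCB4 (chromosome 2, 19306342 to 19321599, a region shared by 6 genes) had both values highest in cluster 4, where its accessibility was 1.42 times its median. Its correlation of 0.891 was the highest among 97 markers. ATHB8 (chromosome 4, 15859268 to 15864471 and 15868301 to 15869979) followed with 0.808, then MCM5 (AT2G07690, chromosome 2, 3527046 to 3527729) with 0.786, CVP2 (chromosome 1, 1606602 to 1608799 and 1611442 to 1612028) with 0.778 and LHW (chromosome 2, 11647412 to 11654897) with 0.765. The lowest values were those of TSO2 (chromosome 3, 9978967 to 9982693) at -0.455, GATA23 (chromosome 5, 9478405 to 9480868) at -0.412, PRP3 (chromosome 3, 23178212 to 23188812) at -0.304, HIS4 (chromosome 2, 12324652 to 12331550) at -0.282, PLT1 (chromosome 3, 7302972 to 7306209) at -0.280 and CASP1 (chromosome 2, 15147683 to 15161495) at -0.260. The sign of the GATA23 value turned with a Pearson correlation, at 0.021. Each of these lowest markers overlapped a region shared by 2 to 4 genes, with 3 for PRP3 and 4 for CASP1. Their accessibility is therefore not that of 1 gene alone. PHO1, ATHB8 and LHW also overlapped a region shared by 2 genes. Accessibility of PRP3 in cluster 1 was 0.952 times its median over clusters, although its expression was highest there.

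Over 12922 genes the median correlation was 0.297, and 3553 genes (27.5%) reached 0.5. In 1000 shuffles of the cluster names the median never exceeded 0.092 and at most 3.72% of genes reached 0.5. With gene positions shifted by 100 kb, as a check of the join, the median was -0.027. Among the fixed lists, the 8 stele genes had the highest median, 0.645 at percentile 99.7, with 6 at 0.5 or more. The 16 wound, touch and immune genes had 0.505 at percentile 98.8. The 17 ribosomal protein genes had -0.078 at percentile 0.02, and 10 of them were below 0. Jasmonate, mineral uptake and non-hair genes had 0.466, 0.487 and 0.468, root hair and oxidative stress genes 0.375 each, mitosis genes 0.409 and endodermis genes 0.313. DNA replication, pericycle, reference, xylem, root cap and phloem genes had 0.255, 0.214, 0.201, 0.197, 0.140 and 0.106, and heat shock and photosynthesis genes -0.057 and 0.012, all within the middle 95% of random lists. The 1 cortex gene had 0.450 and the 2 stem cell niche genes had a median of -0.051. Of 889 genes at least 4-fold above every other cluster in expression, 402 (45.2%) were most accessible in that cluster, compared with 4.77% after the shift. Of the 97 fixed markers, 34 were most accessible in the cluster where they were most expressed. Of the 6 markers with the highest correlation, ATHB8, MCM5, CVP2 and LHW were most accessible in another cluster. The share was 93.9% of 33 genes in cluster 4, 66.7% of 117 in the suberin cluster 14, 62.6% of 99 in cluster 16, 48.5% of 136 in the phloem-like cluster 19, 32.2% of 180 in the mitotic cluster 10, 26.0% of 50 in the pericycle-like cluster 18 and 18.9% of 90 in the xylem-like cluster 21. The lowest shares were 16.7% of 12 in cluster 3, 11.1% of 9 in cluster 9 and 0 of 2 in cluster 8. How often each cluster was the most accessible for genes of any kind was not compared, so these shares do not rank the clusters. Cluster 4 was also the most accessible for some genes most expressed in cluster 8, such as RPL10A (AT1G14320), RPS6A (AT4G31700) and RPP0B (AT3G09200). For 19 of 21 accessibility clusters the best nucleus cluster had the same number, the exceptions being clusters 1 and 7. From the nucleus side it was also 19 of 21, with nucleus clusters 7 and 10 closer to accessibility cluster 9. For the mitotic cluster 10 the correlation was 0.355 there against 0.277 with its own number. As with whole cells, how the accessibility clusters were numbered is not given in the sources used here. If their numbers drew on expression, the agreement by number and the gaps to shuffled names and shifted positions may be partly built in. Regions that overlapped a gene held 2 genes in the median. The mean value of a region over clusters was about 0.620 throughout, with a coefficient of variation of 0.114 over all regions. Levels of different regions were therefore not comparable, and the correlation across genes within a cluster, 0.246 in the median, cannot be read as an effect of accessibility on expression.

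**Figure D4:**
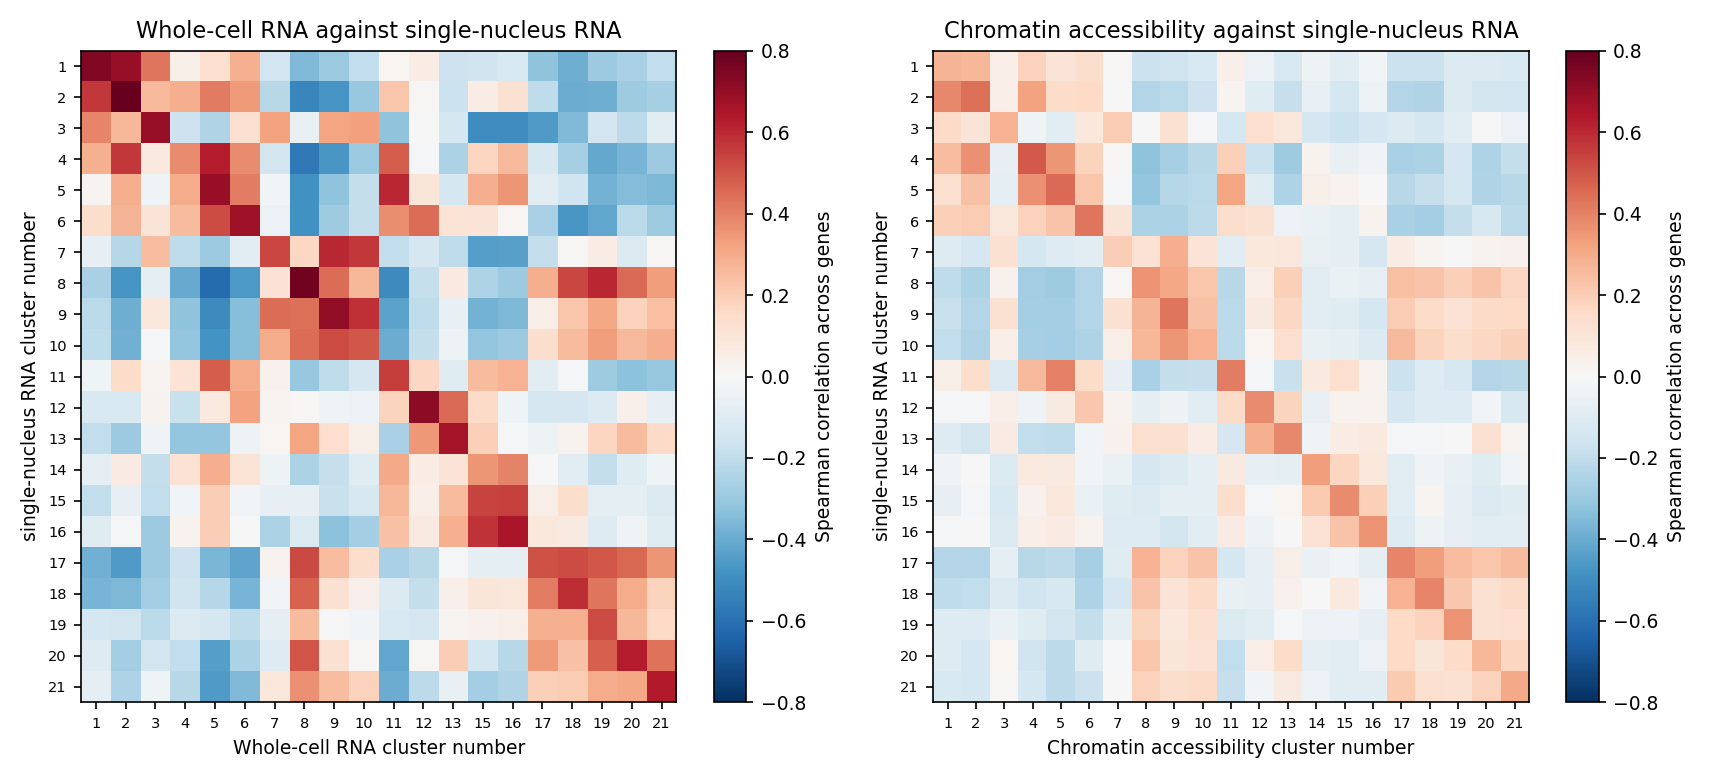
Spearman correlation across genes (colour) between single-nucleus RNA clusters (rows) and whole-cell clusters (left) or accessibility clusters (right), on values centred per gene over clusters. The median on the diagonal was 0.642 for whole cells and 0.376 for accessibility.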

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

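No paired analysis was possible because every group held 1 library or 1 pooled average, and for the same reason leaving out a replicate was not possible. Of the main results, 69 values under alternatives stayed the same and 25 moved. Of the values of single genes and lists, 507 stayed, 184 moved and 1 reversed.

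In the bulk comparison, 2960 genes were lower in protoplasts with 5 FPKM added and 2243 with a floor of 20 FPKM, where fewer genes were compared. Centred ratios gave 2632 higher and 2845 lower (48.1% higher), and a 4-fold threshold 727 and 1465, by construction. Whole cells against nuclei gave 599 genes higher in whole cells and 591 in nuclei with 1 per 10000 added (50.3% higher in whole cells). With no floor 6389 were higher in nuclei (19.8% higher in whole cells), with a floor of 2 per 10000 the counts were 663 and 352 (65.3%), and centred ratios gave 2097 higher in whole cells (52.2%). The direction of that split was therefore not settled. The median whole-cell ratio of protoplast-higher genes was 1.86 with 2-fold lists, 3.37 with 8-fold lists and 1.19 with 1 per 10000 added, and that of protoplast-lower genes was -2.82 with 8-fold lists and -0.64 with 1 added. Every one of these kept its direction. The median accessibility correlation was 0.403 for genes at 2 per 10000 or more and 0.418 for genes alone in their regions, where the correlation within clusters was 0.346. The value of GATA23 reversed to 0.021 with a Pearson correlation. Except where construction is named, the cause was not tested.

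With no floor the bulk percentiles were 1.86 for mitosis, 13.96 for pericycle, 33.1 for photosynthesis, 86.4 for root cap and 2.1 for stem cell niche genes. With a floor of 20 FPKM they were 2.79 for endodermis, 10.8 for pericycle, 7.74 for photosynthesis and 93.9 for xylem genes, so these lists depended on the floor. Using the averages as deposited changed no RNA value, because the columns already sum to 10000, and neither did taking organelle genes out of the total, because the cluster tables list none. For RNA these alternatives were bound to add to the values counted as the same above. They were also the only alternatives for the cluster identities. Leaving out cluster 14, keeping genes listed at 0, matching on length, leaving out genes with shared values and using genes alone in their regions were alternatives chosen after seeing the data. Unknown depth limits what can be said of low genes.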

Other observations

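The tests on clusters 14 and 18 and the length matching of the protoplast genes were chosen only after those patterns were seen, though both length tests were set down before their own values.

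Genes that lead a nucleus cluster differed between the bulk libraries by cluster. The genes that lead cluster 11, among them EARLI1 and AZI1, were the most reduced in protoplasts, with a median log2 ratio of -4.92 and 8 of 10 lower. Those of cluster 15 had a median of -3.02, with 11 of 12 lower, those of the DNA replication cluster 9 had -1.76, with 7 of 7 lower (percentile 0.19, but 5.68 with length matched), and those of the mitotic cluster 10 had -1.62, with 57 of 75 lower. Those of cluster 14 had -1.34, with 19 of 36 lower. Those of clusters 13 and 12 had -1.11 and -0.94, at percentiles of 6.78 and 17.3, and those of the Casparian strip cluster 16 and the root hair-like cluster 1 had -0.97 each, or -0.52 and -0.51 relative to the median gene of -0.46. In the other direction, all 5 genes past the floor that lead cluster 7, the cluster where the root cap genes SMB and BRN1 had their highest value, were higher, with a median of 2.37. Those of cluster 3 had 1.16 with 7 of 9 higher. Cluster 4 had a median of 0.77 with 11 of 27 higher and 5 lower, the non-hair-like cluster 6 had 0.46 with 6 of 30 higher and 5 lower, and cluster 20 had 0.24 with 4 of 23 higher and 1 lower, so that most genes of clusters 6 and 20 changed by less than 2-fold. The medians of clusters 3, 4, 6, 7 and 20 lay at percentile 99.7 or above. No biological explanation was tested for these differences.

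Genes at least 4-fold higher in the protoplast library were higher in whole cells than in nuclei, with a median of 2.66. Gene length did not account for this: the ratio fell with length (correlation -0.561), and the list was short (median 1826.5 bp against 2576 bp), but length-matched random lists had a median of 0.29 and the list stayed at percentile 100. The median was 1 or more in 19 of 20 clusters of the same number, from 0.65 in cluster 1 to 2.92 in cluster 17. That goes against another mix of cell populations only if a number means the same population in both tables. Nucleus clusters 4, 7, 10, 15 and 17 were closer to another number, and a different mix within clusters was not tested. Within the list, genes with a larger bulk ratio had a larger whole-cell ratio, with a correlation of 0.447 across genes (0.397 given length), which was predicted by a response to wall digestion shared by the 2 materials. Over all 6394 genes with both ratios the correlation was 0.443, so the relation was not particular to the list. The value within the list therefore does not single out a shared response. It also does not exclude nuclear against cytoplasmic RNA, plant age, growth conditions or the unknown preparation of the whole cells.

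Of the 122 genes that lead nucleus cluster 14, 33 (27.0%) were listed at 0 in every whole-cell cluster, against 37 of 807 (4.58%) for the other clusters. If counting had left them out of the whole-cell table alone, the protoplast library should have kept them. Only 36 of the 122 genes passed the bulk floor, and their median bulk ratio was at percentile 3.25, or 1.39 with length matched. This was left open. The first form of that test used 3.25 alone and would have favoured counting, and the length-matched value was required only after it was seen. If another part of the root had been sampled, the intact tip library should have held little of these genes, and their median, 2.08 FPKM, was at percentile 0 among genes that lead any cluster at the same nucleus level. That comparison set also replaced a first one, drawn from all genes, which gave percentile 0 here and for many other clusters and could not discriminate. The value speaks for the tip library only. Clusters 19 and 10 were nearly as low, at 0.225 and 0.57, so it does not single out cluster 14. The title of the intact library reads whole root, and if that holds, the premise of this test is lost.

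Of the 33 genes that lead the pericycle-like cluster 18 and pass the floor, 27 were lower in protoplasts and 1 higher, with a median of -3.02. A loss of every inner tissue relative to the other tissues was not borne out, because genes that lead the xylem-like cluster 21 were at percentile 99.94 and those of the phloem-like cluster 19 at 99.67, while those of cluster 16 were at 0. The medians of clusters 21 and 19 were still -0.15 and -0.19, or 0.30 and 0.27 above the median gene, with 16 lower and 9 higher and with 22 lower and 19 higher. Gene length was not borne out either, with the length-matched percentile at 0. Incomplete release of cluster 18 cells and a response of these genes to digestion were not told apart. A difference in tissue between the bulk libraries was not told apart from them either, since the title of the intact library reads whole root.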
